A study of Drosophila melanogaster with 17 samples.

How the data were processed

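Mushroom body neurons of y w flies with UAS-mCD8::GFP and OK107-GAL4 were taken by laser capture microdissection from frozen sections of larvae at -18 h and of pupae at 0 h and 5 h relative to puparium formation. Per the labels, larvae were staged by dye in the food and chosen with dark blue guts, white prepupae gave the 0 h samples, and captures of cell bodies were pooled into 1 sample per array. The RNA was amplified linearly and labelled with biotin for Affymetrix Drosophila arrays. The deposited values are log2 RMA summaries per probe set and array, made by the authors with RMA in Affymetrix Expression Console per the submitters' processing notes. The versions are not given in the sources used here, nor whether all of the arrays were normalised together. Array dates were not available, and no raw image data were used here. The values were used as deposited.

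All 17 columns were assigned to groups from the labels, with 0 unmapped. The file holds 14010 probe sets, of which 44 controls were left out and 13966 tested. Symbols came from the array's annotation and were matched to the RefSeq Release 6 gene table, which served for current names and gene lengths only, so no coordinates are given. A single symbol was found for 12443 probe sets, several for 327 and none for 1196, and 49 single symbols were not in the gene table. Probe sets with several symbols or none stayed in the counts and were left out of named genes and lists. In all 10844 genes had a probe set of their own, and for the 1209 genes with more than 1 the probe set with the highest mean was used. Among these 1209 genes, 11 had probe sets called in opposite directions between -18 h and 0 h, 0 between 0 h and 5 h and 7 between -18 h and 5 h. Among those with a called probe set, 396 of 447, 84 of 87 and 324 of 356 had only some of their probe sets called.

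A linear model with 3 groups was fitted to each probe set with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with statmod 1.5.0. The contrasts were 0 h against -18 h, 5 h against 0 h and 5 h against -18 h, with limma's F test over the successive steps for a difference at any time. All tests were two-sided, and p-values were adjusted by Benjamini and Hochberg over all probe sets of a contrast, with a threshold of 0.05. Every adjusted p given for a gene is limma's, and SE is that of the fitted contrast. Arrays have no read depth, so their number limits the precision. The median change over all probe sets was -0.02, -0.04 and -0.07 log2 in the 3 contrasts in that order.

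Gene lists were fixed before the data were examined. They are ecdysone response, pruning genes named in the literature, proteasome subunits, ubiquitin enzymes, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, apoptosis, autophagy, synaptic vesicle and active zone, ion channels and excitability, mushroom body neuron markers, axon guidance and adhesion, actin regulation, microtubule and motor, small heat shock and stress, antimicrobial and immune, RNA-binding and translation control, signalling of the Wnt, TGF-beta, Notch, EGFR and JNK pathways, and nuclear receptors. Lists of other cell types were glia, neuroblast and cell cycle, fat body, muscle, hemocyte and basement membrane, cuticle and epidermis, salivary gland glue and late puff, and photoreceptor markers. A list of histones had 2 measured genes, under the minimum of 5, and was not tested. Each of the other 28 was tested with limma's camera against all other genes with an inter-gene correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 28 lists. Fry tests whether a list's genes move one way on balance and does not compare them with other genes. By fry 18, 4 and 17 lists passed in the 3 contrasts.

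Genes to be named were chosen by a rule written before the data were examined. Among probe sets past the threshold without overlap between the groups, it takes the 10 largest rises and the 10 largest falls with proper symbols and the 2 largest of each with bare annotation names, per contrast. It adds the 4 members with the smallest p per list and contrast, and the genes EcR, usp, br, Eip74EF, Eip75B, Hr3, Hr4, Hr39, ftz-f1, Eip93F, Sox14, Mical, bol, ey, Fas2, Dronc, Uba1, Imp and chinmo. Eip74EF, Eip75B, Fas2 and Uba1 had no probe set with a single symbol and are not reported. Where a gene is named outside the rule of its contrast, it was chosen after its values were seen.

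Simulated data of the same size and group numbers tested the code. In 67 probe sets each, changes of 1 log2 unit were called in 98.5%, 98.5% and 94.0% of cases in the 3 contrasts and changes of 0.5 in 76.1%, 61.2% and 56.7%, with 6, 10 and 7 unchanged probe sets called. A proteasome list shifted by 0.5 was called, with 0 other lists. The simulated genes varied independently of each other, so this does not show how often camera calls lists falsely where genes move together.

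Replicate numbers were checked for pairing, by correlating the deviations of arrays from their group means, because the labels do not say whether equal numbers mean shared handling. They were not treated as pairs. Further groupings of the arrays were defined from the data. Glue and muscle signal meant a mean of Sgs3, Sgs4, Sgs5, Sgs7 and Sgs8, or of Mlc2, more than 1 log2 unit above the highest pupal array. Low fat body signal meant Obp99b and Lsp2 within the range of the 0 h arrays, a rule added after the values were seen. The spike-in sets were the 2 clusters with the least sum of squares of the mean BioC, BioDn 3-prime and CreX signal. They part at 10.1 log2 with a gap of 0.136 between neighbours. An earlier rule, the largest gap, only parted 1 larval and 1 pupal array from the rest and was given up before any fit used it.

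To ask whether a list's change follows gene length and expression level, its median was compared with 10000 random lists. Length here is the genomic length of a gene, not that of its transcript. A coarse matching in 10 expression and 8 length classes came first. Matching each member to its 30 nearest genes in length and mean expression was added after that result was seen and is the one reported. A match was held too poor to decide when the median length differed more than 1.2 times or the mean by more than 0.3 log2, a rule added after the values were seen. Taking the list medians of both steps with the 0 h arrays split between them was also added after the values were seen.

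The alternatives chosen beforehand were quantile normalisation, median shift, dropping probe sets under a mean of 4.36 log2, array weights, eBayes with trend and robust options, 2 groups per fit, replicate number as fixed or random block, stricter thresholds, treat against a fold change of 1.2, the median of a gene's probe sets, fry, an estimated correlation, splitting the 0 h arrays between the steps and leaving out each array in turn. Those chosen after seeing the data were leaving out larval arrays with glue or muscle signal and the spike-in set as a block or alone.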

Results

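Messenger RNA was measured in mushroom body neurons of Drosophila melanogaster around the start of metamorphosis. The mushroom body is a paired structure of the insect brain known for its role in olfactory learning, and its gamma neurons prune their larval axon branches early in the pupa. The neurons carried membrane-bound GFP driven by OK107-GAL4, a driver line active in these neurons, and their cell bodies were cut from frozen sections of larvae and pupae by laser capture. The 17 arrays fall into 3 groups, with 7 arrays of larvae at -18 h relative to puparium formation, 7 of white prepupae at 0 h and 3 of pupae at 5 h. Each array carried amplified RNA of 1 pool of captures. The labels call the replicates biological and do not give the number of animals per pool, so limma's p-values for probe sets measure the spread between these pooled samples. Camera's p-values for lists with the fixed inter-gene correlation compare a list's genes with all other genes and do not measure that spread alone.

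Array medians ran from 4.32 to 4.43 log2. Pearson correlations across probe sets were 0.960 to 0.988 between larval arrays, 0.982 to 0.992 between 0 h arrays and 0.988 to 0.993 between 5 h arrays, and 0.934 to 0.964 between larval and 0 h arrays (probe sets are not independent replicates). On the first principal component the group means were -29.6 at -18 h, 21.4 at 0 h and 19.3 at 5 h, and the second component held 10.1% of the variance. The number of arrays, 3 at 5 h above all, limits the precision of each comparison.

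Some arrays carried transcripts of other tissues at uneven levels. The mean of the salivary glue genes Sgs3, Sgs4, Sgs5, Sgs7 and Sgs8 was 7.20 log2 in larval array 1, 7.14 in array 4 and 11.5 in array 6, against 3.75 ± 0.0856 (SD, n = 7) at 0 h. The muscle gene Mlc2 reached 11.2 in larval array 6 and 9.37 in array 7, against 4.90 ± 0.141 (SD, n = 7) at 0 h. Larval arrays 2 and 3 had low values of both, with Mlc2 at 4.92 and 5.40. The fat body gene Fbp1 read 5.29 and 5.32 log2 in 0 h arrays 2 and 5, against 6.93 to 7.77 in the other 0 h arrays, and Obp99b read 8.17 in 5 h array 2 against 5.83 and 6.29 in the other 5 h arrays. In larval arrays Obp99b ran from 5.69 to 9.48, with 7.45 and 7.97 in arrays 2 and 3, against at most 6.52 at 0 h, and Lsp2 from 6.20 to 9.30. Larval arrays 1 and 4 alone had Obp99b and Lsp2 within the range of the 0 h arrays. The glia genes repo and wrapper, the former chosen after its values were seen, lay well above the background in every array. repo ran from 6.1 to 7.2 log2 at -18 h, 7.0 to 8.2 at 0 h and 7.3 to 7.7 at 5 h. wrapper went the other way at first, with 8.1 to 8.8, 7.3 to 7.9 and 8.1 to 8.5 in the same order. The ecdysone response genes ImpL1, ImpE2 and Cyp18a1, chosen after their values were seen, read 7.09, 8.08 and 6.46 in 5 h array 3 and at most 3.22, 3.50 and 3.08 in the other 5 h arrays. The arrays also fell into a higher and a lower set by their hybridisation spike-in signal, split at 10.1 log2. The lower set held larval arrays 4, 5 and 6, the 0 h arrays 1, 2 and 3 and all of the 5 h arrays. The 3-prime minus middle difference of the eIF4a control probe sets, a measure of 3-prime bias, was 3.03 ± 0.0845 at -18 h, 2.81 ± 0.202 at 0 h (SD, n = 7 each) and 2.58 ± 0.0121 at 5 h (SD, n = 3). That of the actin control was 3.37 ± 0.330, 3.08 ± 0.366 and 2.76 ± 0.107 in the same order.

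The comparison of 0 h with -18 h asks what differed in these captures between the larva before the late ecdysone pulse, which starts metamorphosis, and the white prepupa. Pooled cell bodies do not tell a change within neurons from a change in the mix of cells captured, here or in the later comparisons. The largest rise under the naming rule was that of Jhbp2, named for juvenile hormone binding, which went from 3.70 ± 0.142 to 9.14 ± 0.114 log2 (SD, n = 7 each), 43.3-fold higher. Its larval level lay not far above the lower quartile of the larval arrays (3.42), so the fold is a lower bound. Ctl2, a choline transporter-like gene, rose 20.2-fold (log2 change 4.33, SE 0.09, adjusted p = 9.87e-19). CngA, a cyclic nucleotide-gated channel subunit, rose by 3.22 log2 units (SE 0.17, adjusted p = 6.6e-12), a lower bound since its larval level lay near the background. The deepest fall was that of Pglym78, a phosphoglycerate mutase, from 10.4 ± 0.105 to 6.41 ± 0.203 log2 (SD, n = 7 each), 16.3-fold lower. Ald1, an aldolase, fell 11.4-fold and MtnA, a metallothionein, 8.07-fold. Of 26 proteasome genes 24 rose (camera adjusted p = 1.58e-20), and 9 of 10 glycolysis genes (2.23e-14), 45 of 68 oxidative phosphorylation genes (4.41e-21) and 26 of 37 cytosolic ribosomal protein genes (1.78e-14) fell.

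Further rises at 0 h under the naming rule were those of MESR6 (9.29-fold), isoQC (8.52-fold), nrv1, a sodium pump beta subunit (7.67-fold), Dtg (7.31-fold), pch2 (6.05-fold), Ypel (5.79-fold) and Snp (5.59-fold), with CG12880 (26.8-fold) and CG33232 (12.5-fold) among genes with bare annotation names. Further falls were those of Ac76E, an adenylyl cyclase (from 5.95 log2 to near the background), CAH1, a carbonic anhydrase (6.79-fold), Rab27 (6.76-fold), UQCR-6.4 (6.38-fold) and prt (6.01-fold), with CG15353 (7.58-fold) and CG7607 (5.72-fold). The fall of hoe1 (6.84-fold) rested on 1 probe set, since the median of its probe sets changed by -0.06 log2 (adjusted p = 0.653, range over 33 alternatives 6.81e-15 to 0.653). Sgs7, a glue gene, fell 6.77-fold (adjusted p = 0.0214) with a larval SD of 2.96, and its call was lost within the higher and the lower spike-in set (0.0672 and 0.0623) and in the robust fit with trend (0.0655), over a range of 0.000818 to 0.0672 in 33 alternatives. Its log2 change of -2.76 was -1.87 without larval array 6 and -0.62 without the larval arrays with glue signal.

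With the median of a gene's probe sets, the changes at 0 h of CngA, isoQC, CG33232, Snp, ImpE1, Hr4, EcR, bol, mamo, klg and beat-IIIc were smaller by over 1.5 times than those given here, with the calls kept.

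In all, 3568 of 13966 probe sets differed (25.5%), 1903 higher and 1665 lower at 0 h. They include 2965 genes with a probe set of their own, 1642 higher and 1323 lower. At least 2-fold differences numbered 307 higher and 250 lower, and 1575 of the called probe sets had no overlap between the groups, where chance gives 0.0583% of all probe sets tested. Called probe sets are selected for separation, so that share is no yardstick for them. Within the higher spike-in set 2867 probe sets differed, 2579 of them shared with the pooled count in the same direction. The lower set gave 2446 with 2229 shared, and the set as a block gave 3792 with 3562 shared. Without the larval arrays with glue or muscle signal 2992 differed, of which 2490 were shared.

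Of the 28 lists tested 8 passed at 0 h, and 4 of them also with an estimated correlation. Of 26 measured proteasome subunits, 24 rose and 0 fell at 0 h, and the counts adjusted over the list alone were also 24 and 0. The list's mean went from 8.15 ± 0.136 to 9.01 ± 0.121 log2 (SD, n = 7 each). Rpt2, an ATPase of the regulatory particle, rose 3.14-fold (adjusted p = 2.63e-10) and Rpn2, a scaffold of its base, 2.34-fold (5.22e-10). Prosalpha6 and Prosalpha5 of the core particle rose 2.05-fold and 1.95-fold. The list's median change was 0.90 (camera adjusted p = 1.58e-20, adjusted p = 0.0438 with an estimated correlation), with 0.90 in the higher and 0.81 in the lower spike-in set (block adjusted p = 3.49e-19) and 0.92 with larval arrays 2 and 3 alone and 0.70 with larval arrays 1 and 4, low in fat body signal.

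Ubiquitin enzymes rose in part, with 12 of 37 higher and 1 lower (12 and 2 adjusted over the list alone). Ubi-p5E and Ubi-p63E, both ubiquitin precursor genes, rose 2.72-fold and 2.28-fold, and ari-2, a ubiquitin ligase, 2.41-fold. The list's median of 0.06 passed (camera adjusted p = 0.0105) but not with an estimated correlation (adjusted p = 0.222). It also did not pass without the larval arrays with muscle signal (adjusted p = 0.0691, range over 29 alternatives 3.67e-06 to 0.222). Of 24 autophagy genes 11 rose and 1 fell (13 and 1 adjusted over the list alone). Atg7 and Atg3, enzymes that attach Atg8 to lipid, both rose, Atg3 2.94-fold (adjusted p = 8.75e-11) and Atg7 to 5.20 log2 from a background level of 2.95 (6.69e-13). The autophagy median was 0.28 (camera adjusted p = 0.000194, adjusted p = 0.181 with an estimated correlation), with 0.25 in the higher and 0.36 in the lower spike-in set.

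Glycolysis genes fell, 9 of 10 measured with 0 rising, and 9 and 0 adjusted over the list alone. Besides Pglym78 and Ald1, Pgi fell 5.92-fold (adjusted p = 1.08e-15) and Pfk, which encodes phosphofructokinase, 3.83-fold (2.44e-13). The list's mean went from 7.54 ± 0.131 to 5.60 ± 0.0966 log2 (SD, n = 7 each), with a median change of -1.95 (camera adjusted p = 2.23e-14, adjusted p = 0.00165 with an estimated correlation). It was -1.92 in the higher and -1.97 in the lower spike-in set (block adjusted p = 1.26e-13) and -1.97 with larval arrays 2 and 3 and -2.06 with larval arrays 1 and 4 alone. The array's GAPDH 3-prime control probe set, which was not part of the test, read 11.4 ± 0.136 at -18 h and 9.43 ± 0.243 at 0 h (SD, n = 7 each).

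Of 68 oxidative phosphorylation genes 45 fell and 0 rose (46 and 0 adjusted over the list alone), and of 37 cytosolic ribosomal protein genes 26 fell and 0 rose (27 and 0). UQCR-6.4 and UQCR-Q of complex III fell 6.38-fold and 2.71-fold, ND-B14.5B of complex I 3.95-fold and COX7B of complex IV 2.93-fold. RpL29 fell 2.90-fold, RpL32 2.52-fold and RpS20 by 1.07 on the log2 scale. The oxidative phosphorylation median was -0.58 (camera adjusted p = 4.41e-21, adjusted p = 0.00715 with an estimated correlation), with -0.59 and -0.56 in the higher and lower spike-in sets (block adjusted p = 1.41e-20). The ribosomal median was -0.47 (camera adjusted p = 1.78e-14, adjusted p = 0.0438 with an estimated correlation), with -0.49 in each set (block adjusted p = 3.51e-14). With larval arrays 2 and 3 alone the medians were -0.53 and -0.50, and with larval arrays 1 and 4 alone -0.67 and -0.53. Both lists hold mostly short genes. Among probe sets with a mean of at least 7 log2, the 57 of the shortest genes had a median change of -0.81, and the 18S control probe set read 9.18 ± 0.128 at -18 h and 7.60 ± 0.354 at 0 h (SD, n = 7 each). The eIF4a 3-prime minus middle difference went from 3.03 to 2.81 in the same step.

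Ecdysone response genes went both ways, with 9 of 29 higher and 6 lower (9 and 7 adjusted over the list alone). Sox14, an ecdysone-induced transcription factor needed for pruning, rose 3.75-fold (adjusted p = 4.1e-09), vri 5.35-fold (5.24e-11), ImpE1 2.31-fold (6.2e-08) and the nuclear receptor gene Hr4 1.97-fold (6.8e-07). The probe set of EcR, the ecdysone receptor, fell 1.55-fold (adjusted p = 0.00887) from 5.78 ± 0.549 to 5.14 ± 0.107 log2 (SD, n = 7 each). That call was lost in the lower spike-in set (adjusted p = 0.372, range over 33 alternatives 6.47e-05 to 0.372), and the other EcR probe set changed by -0.15. The br probe set named by the rule fell 2.22-fold (adjusted p = 3.55e-06), while the other br probe sets changed by 0.09 and -0.10 and the median of its probe sets turned to 0.09. The usp change was -0.22 (adjusted p = 0.129), and Hr3 (-0.13, 0.292), Hr39 (0.03, 0.847), ftz-f1 (-0.27, 0.0715) and Eip93F (0.14, 0.275) did not pass either. The ftz-f1 change passed with the spike-in set as a block (0.0394) and without larval array 4 (0.0273, range over 32 alternatives 0.0273 to 1), and that of usp without larval array 7 (0.0154, range over 33 alternatives 0.0154 to 1). As a list the ecdysone genes did not pass (camera adjusted p = 0.289), and their median of -0.01 and mean of 0.17 differ in sign.

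Of 46 genes known from pruning studies 18 rose and 3 fell (19 and 5 adjusted over the list alone). Some members, bol among them, are known from work on these neurons, so the count is not independent evidence of direction. Dronc, an initiator caspase, rose 3.73-fold (adjusted p = 1.26e-12), IKKepsilon 2.80-fold and heca 2.88-fold. bol, an RNA-binding protein gene, fell 1.65-fold (adjusted p = 7.34e-06). Mical changed by -0.04 (0.726) at a dim level of 4.22 to 4.19 log2, and Imp by -0.08 (0.553). chinmo fell 1.41-fold (adjusted p = 0.0117), a call lost with the median of its probe sets (0.394) and in the lower spike-in set (0.277), over a range of 0.00061 to 0.394 in 32 alternatives. The pruning median of 0.08 passed (camera adjusted p = 0.00289) but not with an estimated correlation (adjusted p = 0.336), with 0.06 in the higher and 0.23 in the lower spike-in set.

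Among 20 nuclear receptors 3 rose and 2 fell (camera adjusted p = 0.944), and Hr78 rose 4.63-fold (4.73e-13). Of 15 apoptosis genes 3 rose and 1 fell (0.401), with Dark 1.84-fold higher and Diap2, a caspase inhibitor, 2.27-fold lower. Of 16 mushroom body neuron markers 1 rose and 6 fell (2 and 8 adjusted over the list alone, camera adjusted p = 0.0926). prt, a vesicular transporter gene, fell from 8.54 ± 0.342 to 5.96 ± 0.352 log2 (SD, n = 7 each), mamo rose 1.77-fold, and ey, a transcription factor gene whose locus holds the driver, changed by -0.31 (0.0701) at a level of 8.97 to 8.66. The ey change passed in some alternatives, namely with the replicate number (0.0167) or the spike-in set (0.0398) as a block, in the higher spike-in set (0.0393), with quantile normalisation (0.0439) and with dim probe sets dropped (0.0494). It also passed without the larval arrays with muscle signal (0.0151), larval array 5 (0.0307) or 6 (0.00963) or 0 h array 7 (0.0163), over a range of 0.00963 to 1 in 33 alternatives. The marker list passed in the higher spike-in set (median -0.28, adjusted p = 0.04), where the lower set had a median of -0.02. It also passed without the larval arrays with muscle signal (0.0321) and without larval array 6 (0.0432), over a range of 0.00126 to 0.479 in 29 alternatives. Of 23 synaptic vesicle and active zone genes 1 rose and 9 fell (1 and 10 adjusted over the list alone, 0.0726), with ChAT 2.29-fold lower and unc-13 1.62-fold higher. The synaptic list passed in the higher spike-in set (0.04), without the larval arrays with muscle signal (0.0221) and without larval array 6 (0.0423) or 0 h array 2 (0.0435), over a range of 0.000194 to 0.265 in 29 alternatives. Of 31 ion channel genes 4 rose and 10 fell (4 and 11, 0.0926), with the GABA receptor subunit Rdl 5.68-fold lower and nAChRalpha2 3.88-fold higher. The channel list passed without the larval arrays with muscle signal (0.021) and without larval array 6 (0.0432), over a range of 0.00395 to 0.479.

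Axon guidance and adhesion genes had 16 of 51 higher and 3 lower (16 and 5 adjusted over the list alone, camera adjusted p = 0.0825), with klg, an immunoglobulin superfamily gene, 3.61-fold and beat-IIIc 2.85-fold higher. Of 25 actin regulators 8 rose and 2 fell (9 and 2, 0.169), with the formin gene dia 3.30-fold higher. The actin list passed without the larval arrays with glue or muscle signal (0.0238) and without those with glue signal alone (0.0486), over a range of 0.00183 to 0.479 in 29 alternatives. Of 37 microtubule and motor genes 9 rose and 3 fell (11 and 4, 0.335). spas, which encodes the severing protein Spastin, rose 4.18-fold, and the futsch probe set fell 5.13-fold, a call lost with the median of its probe sets (0.991, range over 33 alternatives 1.27e-13 to 0.991). Of 15 heat shock and stress genes 7 rose and 4 fell (7 and 5, 0.339), with Hsp26 5.16-fold higher and GstD1 2.66-fold lower. RNA-binding genes had 6 of 33 higher and 4 lower (0.853), and signalling genes of the Wnt, TGF-beta, Notch, EGFR and JNK pathways had 4 of 33 higher and 2 lower (0.853).

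Marker lists of other cell types moved unevenly at 0 h. Of 33 neuroblast and cell cycle markers 14 fell and 2 rose (18 and 3 adjusted over the list alone), PCNA among the former (1.55-fold) and scra and brat the ones that rose (3.37-fold and 3.63-fold). Its median was -0.22 (camera adjusted p = 0.0193, adjusted p = 0.336 with an estimated correlation). The call was lost without the larval arrays with glue or muscle signal (0.397), glue signal (0.0645) or muscle signal (0.154), with dim probe sets dropped (0.145) and without 0 h array 7 (0.0525), over a range of 0.00246 to 0.397 in 29 alternatives. Glia markers had 3 of 19 higher and 5 lower (camera adjusted p = 0.591), fat body markers 2 of 10 higher and 3 lower (0.624, FASN1 2.03-fold, Lsp2 2.85-fold and Obp99b 4.02-fold), muscle markers 3 of 16 higher and 4 lower (0.216) and hemocyte markers 2 of 20 higher and 2 lower (0.782). Cuticle genes had 3 of 110 higher and 1 lower (0.179), glue and late puff genes 0 of 17 higher and 2 lower (0.118), photoreceptor markers 1 of 18 higher and 2 lower (0.801) and immune genes 2 of 16 higher and 3 lower (0.853). The calls of Lsp2 and Obp99b were lost without the larval arrays with muscle signal (0.0531 and 0.113) and in the lower spike-in set (0.0627 and 0.152), over ranges of 0.000254 to 0.0627 and 0.000177 to 0.152 in 33 alternatives. Median and mean differ in sign for apoptosis, nuclear receptor, RNA-binding and hemocyte lists, none of which passed by camera. Cuticle genes passed without the larval arrays with glue signal (0.0142, range over 29 alternatives 0.0142 to 0.764). By fry, which does not compare a list with other genes, 10 lists that did not pass by camera passed at 0 h. They were ecdysone response, nuclear receptors, apoptosis, mushroom body neuron markers, synaptic, ion channel, axon guidance, actin, microtubule and heat shock genes.

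**Figure D1:**
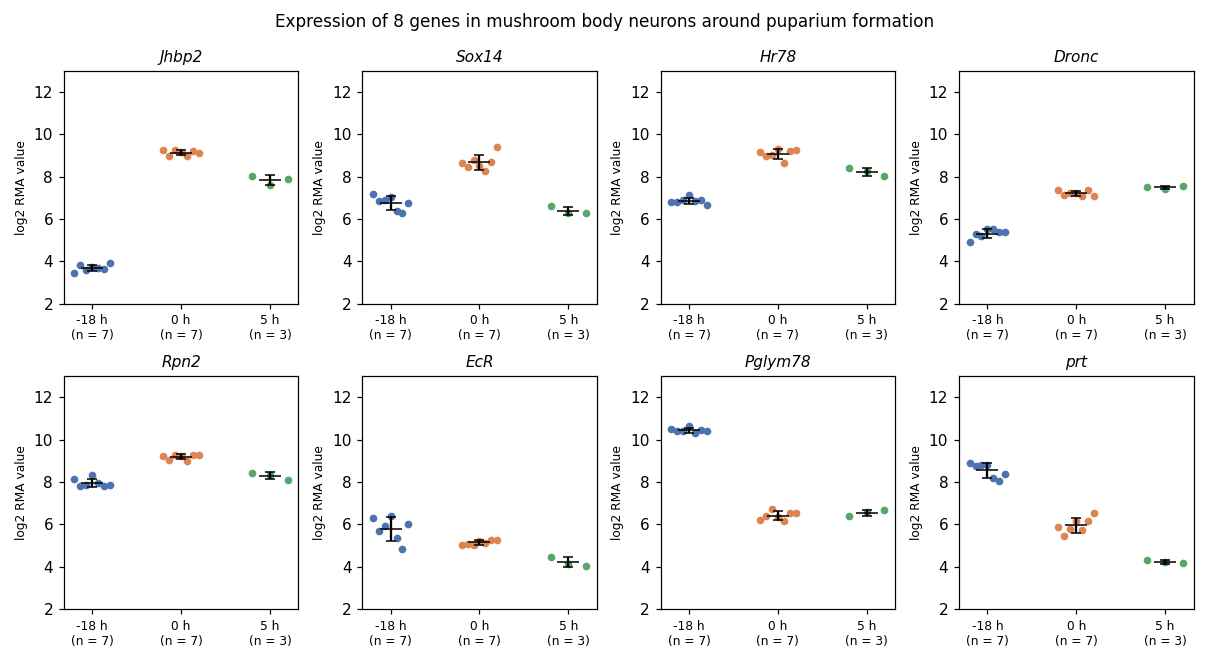
RMA log2 values of 8 genes at -18 h, 0 h and 5 h, with a dot per array and the group mean with SD bars (n = 7, 7 and 3). Jhbp2 stood at 3.70, 9.14 and 7.85 log2, and Pglym78 at 10.4, 6.41 and 6.54.

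The comparison of 5 h with 0 h asks what changed in the first hours after puparium formation, before the gamma neuron branches are lost. CG30053 rose most, from 5.03 ± 0.132 (SD, n = 7) to 8.01 ± 0.0402 log2 (SD, n = 3), 7.89-fold. Sol1 fell furthest, from 8.14 ± 0.334 (SD, n = 7) to 5.02 ± 0.473 log2 (SD, n = 3), 8.69-fold. Sox14, higher at 0 h, fell 4.90-fold to 6.39 log2 (log2 change -2.29, SE 0.20), and klg fell 3.30-fold. MFS3, a major facilitator family gene, and prt fell a further 4.11-fold and 3.31-fold. Of 68 oxidative phosphorylation genes 16 rose, and of 26 proteasome genes 9 fell (list adjusted p = 0.0258 and 0.256 with an estimated correlation), each list against its direction in the step before. With the 0 h arrays split so that none served both steps, the list medians were -0.57 and then 0.25 for oxidative phosphorylation and 0.88 and then -0.42 for the proteasome (medians of 35 splits), with opposite signs in 35 of 35 splits.

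Other rises at 5 h were those of tpr (to 4.38 log2, from a background level of 2.59), bdl, an immunoglobulin superfamily gene (3.37-fold), Treh, which encodes trehalase (2.99-fold), wun2, a lipid phosphate phosphatase (2.99-fold), Lip4 (2.78-fold), cer (2.68-fold), CngA (log2 change 1.40) and Cad96Cb (2.53-fold). Asph rose 4.42-fold and Sirup 3.45-fold, with 5 h SDs of 0.951 and 0.774 log2 (n = 3). CG5080 rose 2.93-fold with an SD of 1.23, a log2 change of 1.55 that was 2.18 without 5 h array 1 and 0.95 without array 3, and its call was lost in the lower spike-in set (adjusted p = 0.119, range over 32 alternatives 8.24e-07 to 0.119). Other falls were those of Dh44-R1, a neuropeptide receptor (4.69-fold), rdo (from 5.26 to 3.39 log2, near the background), Sply, a sphingosine-1-phosphate lyase (3.24-fold), Svil (3.21-fold), CG12910 (3.29-fold) and CG32647 (2.61-fold). sals fell 7.09-fold with a 5 h SD of 1.62 log2 (n = 3), a log2 change of -2.83 that was -2.24 without 5 h array 2 and -3.75 without array 3. The Sol1 call was lost with the median of its probe sets (adjusted p = 0.884, range over 32 alternatives 7.86e-11 to 0.884). By the same median, the changes of CngA, Cad96Cb, Asph, Svil, CG32647, sals, klg, Hr4, ImpE1 and Fhos at 5 h were smaller by over 1.5 times than those given here, with the calls kept.

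In all, 527 of 13966 probe sets differed (3.77%), 329 higher and 198 lower at 5 h, or 450 genes, 286 higher and 164 lower. At least 2-fold differences numbered 44 higher and 45 lower, and 479 called probe sets had no overlap, where chance gives 1.67% of all probe sets tested, not of those called. The count was 332 without 5 h array 1, 311 without array 2 and 304 without array 3, of which 298, 294 and 289 were shared. All of the 5 h arrays were in the lower spike-in set, where 400 probe sets differed, 179 higher and 221 lower, with 282 shared. As a block the sets gave 511, 260 higher and 251 lower, with 395 shared, so the excess of rises depends on this choice.

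Of the lists 5 of 28 passed at 5 h, or 8 without 5 h array 1, and 1 also passed with an estimated correlation. Of 68 oxidative phosphorylation genes 16 rose and 0 fell at 5 h (31 and 0 adjusted over the list alone). UQCR-6.4 rose 2.03-fold (adjusted p = 0.000369), ND-B12 of complex I 1.65-fold (0.000237), COX7B 1.56-fold (0.000641) and ATPsynCF6 of the ATP synthase 1.47-fold (0.000278). The list's median was 0.28 (camera adjusted p = 2.45e-18, adjusted p = 0.0258 with an estimated correlation), and 0.23 in the lower spike-in set (block adjusted p = 9.36e-18). Its mean went from 6.46 ± 0.0515 (SD, n = 7) to 6.72 ± 0.0565 log2 (SD, n = 3). Of 37 ribosomal protein genes 4 rose and 0 fell (10 and 1 adjusted over the list alone), with RpL23 1.62-fold higher (adjusted p = 1.79e-05). The ribosomal median was 0.16 (camera adjusted p = 2.73e-06, adjusted p = 0.426 with an estimated correlation, 0.0522 by fry), and 0.19 in the lower spike-in set (block adjusted p = 2.26e-07). The BioDn spike-in, whose 5-prime minus 3-prime difference was -0.783 ± 0.479 at 0 h (SD, n = 7), read -1.93 ± 0.136 at 5 h (SD, n = 3), and the eIF4a 3-prime minus middle difference went from 2.81 to 2.58. Among probe sets with a mean of at least 7 log2, the 57 of the shortest genes had a median change of 0.36 and the 121 of genes over 10000 bp one of -0.17. Lists of like length and expression had a median of 0.06 for oxidative phosphorylation (95% of lists 0.00 to 0.13, the list at percentile 100). For ribosomal genes it was also 0.06 (-0.02 to 0.12, percentile 99.4), where the matches were dimmer (8.47 against 8.82 log2). By the coarser matching chosen first the ribosomal median lay within the range of matched lists (median 0.10, 95% of lists 0.01 to 0.21, percentile 87.6).

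Of 26 proteasome subunits 9 fell and 0 rose (18 and 0 adjusted over the list alone). Rpn3 fell 1.89-fold (adjusted p = 8.71e-05), Rpn2 1.85-fold (3.12e-05), Rpn12 1.79-fold (7.38e-05) and Rpn7 1.60-fold (0.000241), all of the regulatory particle. The list's median was -0.43 (camera adjusted p = 7.11e-14, adjusted p = 0.256 with an estimated correlation), and -0.45 in the lower spike-in set (block adjusted p = 1.35e-13). Its mean of 8.60 ± 0.0697 log2 (SD, n = 3) lay between those at -18 h and 0 h. Mushroom body neuron markers had 3 of 16 lower and 1 higher (5 and 1 adjusted over the list alone), with prt lower and toy, a Pax6 gene, 1.76-fold higher. The toy call was lost in the lower spike-in set (adjusted p = 0.113, range over 32 alternatives 0.000612 to 0.145). Their median was -0.19 (camera adjusted p = 0.00909, adjusted p = 0.426 with an estimated correlation), and -0.21 in the lower spike-in set (block adjusted p = 0.0141).

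Fat body markers passed as a list with a median of 0.50 (camera adjusted p = 0.0252), though 0 of 10 passed singly in limma and 2 had an unadjusted p under 0.05. Fbp1 changed by 1.25 (adjusted p = 0.246). The call was lost with an estimated correlation (adjusted p = 0.426), by fry (0.117), with dim probe sets dropped (0.0965), with quantile normalisation (0.0863), as a block (0.131), in the lower spike-in set (0.156) and without 5 h array 2 (0.242), 0 h array 5 (0.0695) or 0 h array 7 (0.059), over a range of 0.00777 to 0.426 in 28 alternatives.

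Of 29 ecdysone response genes 6 fell and 1 rose at 5 h (6 and 2 adjusted over the list alone, camera adjusted p = 0.105). The list's mean was 5.13 log2 in 5 h array 3, where ImpL1, ImpE2 and Cyp18a1 were high, against 4.74 and 4.66 in arrays 1 and 2. Without array 3 the list passed with a median of -0.14 (adjusted p = 0.0119). It also passed with dim probe sets dropped (0.000545), by fry (0.0279), with the replicate number as a fixed block (0.0422) and without the larval arrays with glue signal (0.0498), over a range of 0.000545 to 0.464 in 28 alternatives. vri fell 2.81-fold (adjusted p = 3.34e-05) and Hr4 1.73-fold (0.00216), while ImpE1 rose 2.19-fold (7.09e-05). EcR fell 1.91-fold (adjusted p = 0.0203), a call lost with the median of its probe sets (0.0806), as a block (0.0845), in the lower spike-in set (0.221) and without 5 h array 2 (0.103) or 3 (0.133), over a range of 3.32e-05 to 0.244 in 32 alternatives. The br probe set fell 1.89-fold (adjusted p = 0.00718), which the median of its probe sets did not show (0.481, range over 32 alternatives 0.000135 to 0.481). Of 46 pruning genes 2 rose and 5 fell (3 and 6, camera adjusted p = 0.298, but 0.0349 with the spike-in set as a block, range over 28 alternatives 0.0349 to 0.762), with Rpn6 1.54-fold and Sox14 4.90-fold lower. The changes of Mical (-0.10, 0.698), bol (0.19, 0.582), Dronc (0.29, 0.238), usp (-0.16, 0.663), ftz-f1 (0.32, 0.286), Imp (-0.22, 0.359), ey (0.09, 0.887), Eip93F (-0.20, 0.435), Hr3 (0.03, 0.941), Hr39 (-0.23, 0.398) and chinmo (0.22, 0.688) did not pass. Another Mical probe set of similar level changed by 0.48 (adjusted p = 0.343). The Imp change passed in the lower spike-in set (0.0382, range over 31 alternatives 0.0382 to 1).

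Of 31 ion channel genes 1 rose and 5 fell (1 and 7 adjusted over the list alone, camera adjusted p = 0.158), with the glutamate receptor subunit GluRIA 1.96-fold higher. Glycolysis genes had 0 of 10 higher or lower (0.21), also 0 at an unadjusted p under 0.05 in limma, and autophagy genes 0 of 24 (0.105), with 0 higher and 3 lower unadjusted. The autophagy list passed as a fall in the lower spike-in set (median -0.18, adjusted p = 0.00842), with the spike-in set (0.0349) or the replicate number (0.0111) as a block, with quantile normalisation (0.0305) and without 5 h array 1 (0.0193), over a range of 0.00842 to 0.49 in 28 alternatives. Actin regulators had 3 of 25 higher and 0 lower (5 and 2, 0.107), with Fhos, a formin gene, 1.81-fold higher. Glia markers had 3 of 19 higher (3 and 1, 0.107), wrapper 1.70-fold and nrv2 2.12-fold among them. The wrapper call was lost in the lower spike-in set (0.101, range over 32 alternatives 0.000148 to 0.102) and that of nrv2 without 5 h array 3 (0.0601, range 0.000594 to 0.0848). Nuclear receptors had 1 of 20 higher and 3 lower (0.34), with Hr78 1.80-fold lower (0.000248). Microtubule genes had 0 of 37 higher and 2 lower (0.575), axon guidance genes 2 of 51 higher and 1 lower (0.78) and ubiquitin enzymes 1 of 37 higher and 1 lower (0.996). Immune genes had 2 of 16 higher and 1 lower (0.21), photoreceptor markers 0 of 18 higher and 2 lower (0.107), muscle markers 1 of 16 higher (0.575), signalling genes 1 of 33 higher (0.676), cuticle genes 1 of 110 lower (0.277) and heat shock genes 1 of 15 higher (0.902). By limma 0 genes passed in the synaptic (camera adjusted p = 0.232), apoptosis (0.299), neuroblast (0.739), hemocyte (0.107), glue (0.739) and RNA-binding (0.739) lists, with 4, 5, 3, 2, 0 and 2 genes at an unadjusted p under 0.05. Some of these lists passed in single alternatives. Immune genes did so without 5 h array 3 (0.00885, range over 28 alternatives 0.00885 to 0.608), glia markers without 5 h array 1 (0.0463, range 0.0463 to 0.517) and photoreceptor markers with the median of a gene's probe sets (0.0488, range 0.0488 to 0.464). Hemocyte markers did so without larval array 5 (0.0417), without 5 h array 1 (0.0376) and with the replicate number as a block (0.0422), over a range of 0.0376 to 0.49. For ubiquitin and axon guidance genes the median and camera's direction differ in sign, and for heat shock, glia and muscle lists the median differs in sign from the mean and camera's direction.

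**Figure D2:**
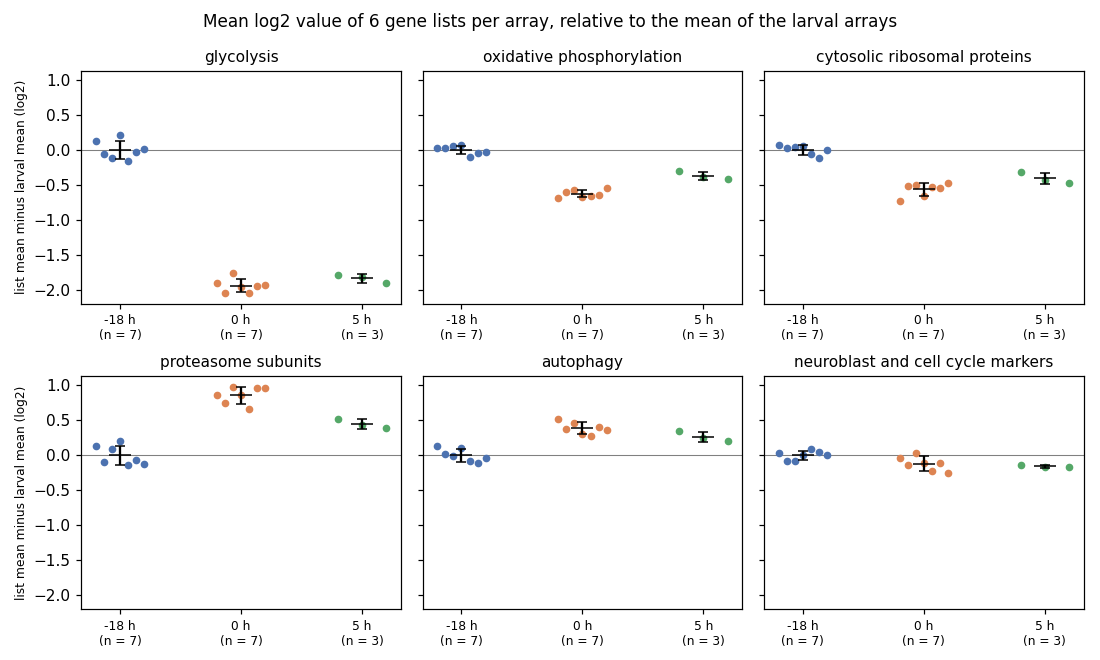
Means of 6 gene lists per array minus the list's larval mean, in log2 units, with a dot per array and the group mean with SD bars (n = 7, 7 and 3). Median changes from -18 h to 0 h and from 0 h to 5 h were 0.90 and -0.43 for the proteasome and -0.58 and 0.28 for oxidative phosphorylation.

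The comparison of 5 h with -18 h asks what had changed over the whole interval. CG12880 was 31.9-fold, Ctl2 18.3-fold, Jhbp2 17.8-fold and CG30053 15.8-fold higher at 5 h (for Jhbp2 again a lower bound). CngA rose by 4.62 log2 units, also a lower bound. prt was lowest relative to the larva, at 4.23 ± 0.0912 log2 (SD, n = 3) against 8.54 ± 0.342 (SD, n = 7), 19.9-fold lower. Sol1 fell 19.0-fold, MFS3 15.6-fold, Pglym78 14.9-fold, CG34166 11.2-fold (log2 change -3.48, and -4.14 without the larval arrays with glue signal), Rdl 9.47-fold and Ald1 9.12-fold. isoQC rose by 3.75 log2 units, nrv1 9.85-fold, Hsp26 8.60-fold, pch2 8.02-fold and Ace, which encodes acetylcholinesterase, 6.41-fold. The Sol1 value rests on 1 probe set, since the others changed by -0.13 (adjusted p = 0.516) and -0.48 (0.00329). EcR was 2.97-fold lower (adjusted p = 2.56e-05) by the probe set used and changed by -0.19 (0.212) by the other. Dronc was 4.55-fold higher (1.66e-11), while Sox14 changed by -0.39 (0.185) and Hr4 by 0.19 (0.403, but 0.0205 in the lower spike-in set, range over 32 alternatives 0.0205 to 1). bol changed by -0.53 (0.0045) by the probe set used and by -0.20 (0.213) by the other. chinmo changed by -0.27 (0.317), but passed without the larval arrays with muscle signal (0.0294). Imp did not pass, but did so with the spike-in set as a block (0.0142), with 2 groups per fit (0.0279) and in further alternatives. Mical changed by -0.14 (adjusted p = 0.277), and another of its probe sets by 0.65 (0.0488). br fell 4.19-fold (adjusted p = 8.25e-08), a call lost with the median of its probe sets (0.517, range over 32 alternatives 1.54e-09 to 0.517). CAP fell 6.51-fold, but the median of its probe sets changed by 0.03. By that median the changes of CngA, isoQC, Prosalpha7, EcR and Sol1 were smaller by over 1.5 times than those given, with the calls kept.

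In all, 2799 of 13966 probe sets differed, 1533 higher and 1266 lower at 5 h, or 2302 genes, 1323 higher and 979 lower. At least 2-fold differences numbered 322 higher and 189 lower, and 2304 called probe sets had no overlap, where chance gives 1.67% of all probe sets tested, not of those called. In the lower spike-in set 2128 differed with 1889 shared, and with the set as a block 2292 with 2137 shared. Without the larval arrays with glue or muscle signal the count was 2873, with 1349 higher and 1524 lower.

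Of the lists, 13 of 28 passed between -18 h and 5 h, and only glycolysis also with an estimated correlation. Its 9 falls of 10 (9 adjusted over the list alone) had a median of -1.72 (camera adjusted p = 9.04e-14, adjusted p = 0.00166 with an estimated correlation), and -1.70 in the lower spike-in set. Oxidative phosphorylation genes had 32 of 68 lower (33 adjusted over the list alone) with a median of -0.31 (camera adjusted p = 4.73e-09, adjusted p = 0.169 with an estimated correlation), and -0.30 in the lower set. Ribosomal protein genes had 18 of 37 lower (24 adjusted over the list alone), RpS29 4.42-fold, with a median of -0.33 (camera adjusted p = 6.44e-07, adjusted p = 0.21 with an estimated correlation) and -0.25 in the lower set. Proteasome genes had 18 of 26 higher and 1 lower (20 and 1) with a median of 0.44 (camera adjusted p = 5.08e-09, adjusted p = 0.21 with an estimated correlation) and 0.46 in the lower set. Among probe sets with a mean of at least 7 log2, the 57 of the shortest genes had a median change of -0.36 over this interval. Prosalpha7 was 2.09-fold higher and Rpn12, named after its values were seen, the 1 that fell, 1.62-fold.

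Mushroom body neuron markers had 6 of 16 lower and 1 higher (8 and 1 adjusted over the list alone), prt and Dop1R1, a dopamine receptor gene (2.08-fold), among those that fell (median -0.29, camera adjusted p = 0.00729, adjusted p = 0.237 with an estimated correlation). Synaptic genes had 5 of 23 lower (5 adjusted over the list alone), with ChAT 2.12-fold lower and a log2 change of -0.58 for EndoA, an endophilin gene (median -0.23, camera adjusted p = 0.00755, adjusted p = 0.198 with an estimated correlation). Autophagy genes had 8 of 24 higher and 2 lower (8 and 2), with Atg7 at 4.94 log2 against a background level of 2.95 in the larva (median 0.17, camera adjusted p = 0.00755, adjusted p = 0.28 with an estimated correlation). Actin regulators had 7 of 25 higher and 1 lower (8 and 2), with dia 2.53-fold and cib 2.38-fold higher (median 0.17, camera adjusted p = 0.00755, adjusted p = 0.21 with an estimated correlation). In the lower spike-in set the medians were -0.16, -0.18, 0.15 and 0.15 in that order, with block adjusted p of 0.00362, 0.00362, 0.0145 and 0.0491. The autophagy median lay within the range of lists of like length and expression (percentile 88.6).

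The other 5 lists lost the call in further alternatives besides an estimated correlation. Among them the ubiquitin, pruning and ion channel medians lay within the range of lists of like length and expression (percentiles 96.3, 94.9 and 11.6). Ubiquitin enzymes had 9 of 37 higher and 1 lower (9 and 1 adjusted over the list alone, camera adjusted p = 0.0109, adjusted p = 0.218 with an estimated correlation), lost without the larval arrays with muscle signal (0.0842, range over 28 alternatives 0.00018 to 0.218). Neuroblast markers had 12 of 33 lower and 3 higher (19 and 3, camera adjusted p = 0.0154, adjusted p = 0.28 with an estimated correlation), lost without the larval arrays with glue or muscle signal (0.289), glue signal (0.0508) or muscle signal (0.117) and with dim probe sets dropped (0.068), over a range of 0.000653 to 0.289. Pruning genes had 15 of 46 higher and 4 lower (17 and 6, camera adjusted p = 0.0254, adjusted p = 0.413 with an estimated correlation), lost with the spike-in set (0.11) or the replicate number (0.0881) as a block, without the larval arrays with muscle signal (0.133), with quantile normalisation (0.0635) and with dim probe sets dropped (0.0505), over a range of 0.00583 to 0.413. Ion channels had 10 of 31 lower and 3 higher (12 and 3, camera adjusted p = 0.0433, adjusted p = 0.401 with an estimated correlation), lost in the lower spike-in set (0.0988), with dim probe sets dropped (0.0854), with the median of a gene's probe sets (0.17) and without larval array 2 (0.0536) or 4 (0.0938), 0 h array 7 (0.0502) or 5 h array 3 (0.0544), over a range of 0.000701 to 0.401. Cuticle genes had 6 of 110 lower and 3 higher (0 and 2, camera adjusted p = 0.0433, adjusted p = 0.606 with an estimated correlation), lost with the spike-in set (0.115) or the replicate number (0.13) as a block, in the lower set (0.0608), by fry (0.0694), without the larval arrays with muscle signal (0.151) and without larval array 3 (0.0616), 5 (0.0583), 6 (0.0784) or 7 (0.0828) or 5 h array 1 (0.0709) or 2 (0.108), over a range of 0.00312 to 0.606.

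The lists that did not pass over the whole interval were ecdysone response (7 of 29 higher and 6 lower, camera adjusted p = 0.893), axon guidance (11 of 51 and 3, 0.0675), microtubule (8 of 37 and 3, 0.494), heat shock (5 of 15 and 4, 0.397), apoptosis (3 of 15 and 1, 0.148), nuclear receptors (3 of 20 and 2, 0.952), immune (5 of 16 and 2, 0.198) and glia genes (5 of 19 and 1, 0.673). The same held for fat body (3 of 10 higher and 1 lower, 0.489), muscle (2 of 16 and 2, 0.397), hemocyte (3 of 20 and 1, 0.507), glue (0 of 17 and 0, with 4 lower at an unadjusted p under 0.05 in limma, 0.086), photoreceptor (0 of 18 and 2, 0.148), RNA-binding (3 of 33 and 4, 0.952) and signalling genes (4 of 33 and 4, 0.893). Immune genes passed without 5 h array 3 (0.0302, range over 28 alternatives 0.0302 to 0.459), and glue genes with the spike-in set as a block (0.0491) and without larval array 5 (0.0434, range over 27 alternatives 0.0434 to 0.509). By fry the immune, apoptosis, axon guidance, photoreceptor and heat shock lists passed as well. Median and mean differ in sign for the ecdysone, microtubule, heat shock, glia, hemocyte and RNA-binding lists.

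Over both successive steps together, 3790 probe sets (27.1%) differed at some time by limma's F test, and 370 passed in each step. Sox14, klg, Hr78 and vri rose and then fell, as did 114 probe sets in all. UQCR-6.4, Treh and Sirup fell and then rose, as did 148. CngA, ImpE1 and CG30053 were among 67 that rose in each step, and prt, MFS3 and Sol1 were among 41 that fell in each. Since the 0 h arrays enter both steps, the count was also taken with them split between the steps. Over 35 splits the median was 215 (164 to 297), where the calls of the split fits would give a median of 68.5 (at most 114) if the steps were independent, and 35 of 35 splits exceeded their own value. That value takes all probe sets as equally likely to be called, and the splits reuse the same arrays. The excess does not by itself show that the changes of the steps are linked. Without 5 h array 1, 2 or 3 the count was 216, 226 or 215, and it was 391 with the spike-in set as a block and 270 in the lower set.

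**Figure D3:**
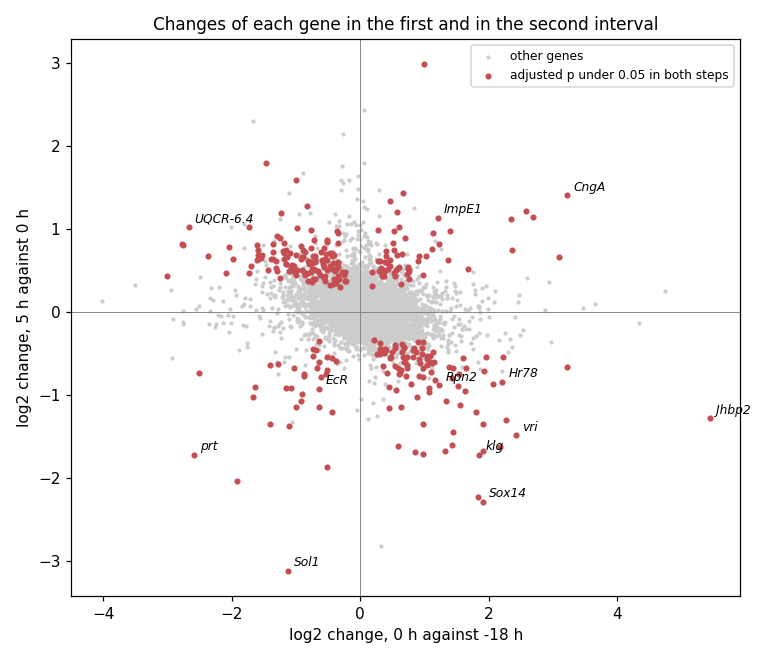
Each dot is a gene, shown by its probe set with the highest mean. Its log2 change from -18 h to 0 h is on the x axis and that from 0 h to 5 h on the y axis. Red dots passed at an adjusted p under 0.05 in both steps. Over all 13966 probe sets tested, some of which are not drawn, 370 passed in both steps. Of these 370 probe sets, 148 fell and then rose and 114 rose and then fell.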

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

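Among the tests in this part, those on members with a mean of at least 7 log2, the nearest-neighbour matching, the rule on how close a match must be, the fat body test and the spike-in test on arrays left out were chosen after the first result was seen. All others were written down before it.

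The fall of oxidative phosphorylation and cytosolic ribosomal protein genes from -18 h to 0 h was weighed because short genes fell as a class, and the oxidative phosphorylation median of -0.58 lay at percentile 0 of 10000 lists of like length and expression (median -0.05, 95% of lists -0.13 to 0.03). For its 38 members with a mean of at least 7 the median of -0.81 was again at percentile 0. Both values argue against a trend with genomic length and level. Transcript length was not matched, so a trend with it was not tested. With larval arrays 2 and 3 alone, which have low glue and muscle signal, the fall was 0.9145 of that with all larval arrays, with arrays 1 and 4 alone, low in fat body signal, it was 1.149, and the smaller value within a spike-in set was 0.9641 of the pooled fall. The ribosomal fall gave 1.058, 1.135 and 1.036 in the same tests, but it cannot be told apart from the length and level trend. Its median of -0.47 was at percentile 0, and at 0.02 for members with a mean of at least 7. But its matches stayed longer and dimmer (1290 against 1099 bp and 8.47 against 8.82 log2), so the bound set beforehand was too weak. A change with developmental stage stays open as an untested hypothesis for each list. Handling or amplification shared by the arrays of a stage cannot be told apart from it.

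The fall of glycolysis genes at 0 h was weighed since the GAPDH control probe set fell with it, from 11.4 to 9.43 log2. The list's median of -1.95 was at percentile 0 of lists of like length and expression (median 0.11, 95% of lists -0.14 to 0.51). It was 1.013 of its size with larval arrays 2 and 3 alone, 1.055 with arrays 1 and 4 alone, low in fat body signal, and at least 0.9841 of it within each spike-in set. These values argue against a trend with genomic length, though transcript length was not matched, and against the spike-in sets as the whole cause. They also argue against muscle and salivary gland RNA alone, or fat body RNA alone, in the larval captures as the whole cause. A mix of these tissues was not tested, since arrays 2 and 3 had Obp99b above the 0 h arrays and arrays 1 and 4 had glue signal. Glial RNA, seen in all arrays by repo and wrapper, was not tested as a cause of this fall or of other changes. A lower level of these transcripts in the neurons at puparium formation may be a candidate explanation, found and tested on the same data and not tested apart from stage. Handling or amplification shared by the arrays of a stage, or a changed mix of captured cells, cannot be told apart from it. The 18S control read 8.98 to 9.31 log2 in larval and 7.02 to 8.05 in 0 h arrays, and array dates were not available.

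The differences between 5 h and 0 h were weighed because every 5 h array was in the lower spike-in set and had a low BioDn 5-prime control. The share of 0.9815 of the median change kept within that set by the 527 probe sets called decides nothing, as they were called on the same arrays, so probe sets were called between 2 of the 5 h arrays and the 0 h arrays of the higher set, and then measured between the 5 h array left out and the 0 h arrays of its own set, where the sets as the whole cause would leave no change. With 5 h array 1, 2 or 3 left out, 219 of 225, 214 of 221 and 228 of 236 kept their direction, with 0.753, 0.761 and 0.822 of the median change, which argues against the sets as the whole cause. The 0 h array 1, with the BioDn difference of the 5 h arrays, lay at a median position of -0.0126 between the other 0 h arrays (0) and the 5 h arrays (1) over 471 probe sets called without it, and the other 0 h arrays lay at -0.0462 to 0.155. Handling shared by the 5 h arrays cannot be told apart from the 5 h stage, since 1 array excludes nothing and no other 0 h array shares the low control, and a change with age stays open and untested.

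Other splits of the same arrays, 100 for each result with the real one included, were refitted. For 3568 probe sets between -18 h and 0 h the highest other was 1961, from a split that differs from the real one by 1 array per group exchanged, and 1 of the 100 splits was as large, the real one, so chance can be excluded. Chance can also be excluded for 527 between 0 h and 5 h (highest other 2), 2799 between -18 h and 5 h (386), 3790 at any time (825) and 370 in both steps (0), each with 1 split as large. For the count in both steps this does not address the link from the 0 h arrays that both steps share. Nor can such splits tell stage from handling shared by the arrays of a group. The number of gene lists did not exclude chance for 8 lists at 0 h (highest other 12, with 24 splits as large) or for 5 lists at 5 h against 0 h (9, with 29), and did so for 13 lists at 5 h against -18 h (13, with 2). The median over the other splits was 5, 3 and 6 lists in that order.

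Single arrays lying apart from the other 6 of their group by Dixon's test numbered 28 of 392 tested values (7.14%), where chance gives about 1 in 20. Among larval arrays, the value in log2 and that of the nearest other array follow. Array 1 had Dtg at 6.17 (5.07) and cib at 5.50 (5.93). Array 4 had Diap2 at 7.61 (7.05), klg at 8.21 (7.78), Hsf at 7.03 (6.44) and wrapper at 8.81 (8.34). Array 5 had UQCR-Q at 10.05 (10.2) and the hemocyte list mean at 4.35 (3.95). Array 6 had GstD1 at 9.57 (8.48), bt at 6.22 (5.37) and the mean of the glue and late puff list at 6.54 (4.72). Array 7 had pch2 at 6.98 (7.36) and Rpn6 at 8.04 (8.38).

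The 0 h array 7 was lowest for 7 values, namely CngA at 5.51 (nearest 6.31), nrv1 at 7.16 (7.59), CG12880 at 8.53 (8.90), chinmo at 3.09 (3.75), unc-13 at 9.16 (9.57), nrv2 at 3.81 (4.86) and Ace at 9.29 (9.95). The 0 h array 2 had Pfk at 5.26 (5.56), Fhos at 3.98 (3.70) and drpr at 9.37 (8.85), and array 3 had GluRIA at 6.52 (6.31), Asph at 3.72 (3.95) and the heat shock list mean at 6.86 (6.81). Array 5 had Ubi-p5E at 11.4 (11.7). Array 1 had a BioDn 5-prime minus 3-prime difference of -1.86 (nearest -0.69).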

How the results depend on the processing

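Leaving out larval arrays with glue or muscle signal and the spike-in sets were chosen after seeing the data, the other alternatives before it. Of 160 named genes 137, 76 and 132 were called between -18 h and 0 h, 0 h and 5 h, and -18 h and 5 h, and 115, 36 and 107 kept direction and call in all alternatives, as did 4 of 8, 1 of 5 and 1 of 13 lists. Over all gene values 63, 175 and 94 lost the call and 26, 33 and 44 gained one. With the median of a gene's probe sets 4 values changed sign: CAP to 0.0395 at 0 h and 0.0311 at 5 h against -18 h, br to 0.0881 at 0 h and hoe1 to -0.0578 at 5 h against 0 h, as other probe sets of these genes did not move alike.

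Stricter thresholds lower counts by construction. Changes of at least 2-fold numbered 557, 89 and 511 in the 3 comparisons and 615 at any time. By treat against 1.2-fold there were 1548, 130 and 1087. At an adjusted p under 0.01, 264 passed at 5 h against 0 h, 1783 at 5 h against -18 h and 180 in both steps. Array weights gave 1265 at 5 h against 0 h, including all 527, and 4249 (1991 higher, 2258 lower) at 5 h against -18 h; the cause was not tested. Splitting the 0 h arrays, which leaves fewer per step, gave a median of 215 in both steps. An estimated correlation left 4, 1 and 1 lists, fry called 18 at 0 h against -18 h, and the replicate number as a fixed block called 8 at 5 h against 0 h, for which the cause was not tested. Replicate numbers did not pair the arrays, since deviations of equal numbers correlated at -0.281 to 0.367 between -18 h and 0 h, with 1 of 7 best with its own number. As a fixed block they gave 3623, 399 and 2682 probe sets.

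Leaving out each array gave 3270 to 3953 probe sets at 0 h against -18 h, 304 to 562 at 5 h against 0 h, 1938 to 3274 at 5 h against -18 h, 3365 to 4183 at any time and 215 to 403 in both steps. The lists numbered 7 to 11, 4 to 8 and 12 to 13. The lowest counts at 5 h against 0 h and in both steps came without a 5 h array, where fewer arrays remain. Within 1.5 times were quantile normalisation (3730, 546 and 2678), median shift (3572, 528 and 2604), the robust fit with trend (3536, 480 and 2768), dim probe sets dropped (3047, 573 and 2411), and leaving out larval arrays with glue (3843, 653 and 3367) or muscle signal (2648, 586 and 2205). Values near the background of about 3 log2, such as tpr or Hr39 before 5 h, bound small changes poorly.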

Other observations

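Further gene groups, 13 in all, were chosen after the values had been seen and tested like the lists, with p adjusted over these 13. The adjustment does not cover that choice, so these p-values are not independent evidence. Genes of mitochondrial ribosomal proteins fell at 0 h, 38 of 64 with 4 rising (median -0.39, camera adjusted p = 5.78e-13, adjusted p = 0.0184 with an estimated correlation), at percentile 0 of lists of like length and expression (median -0.11). Subunits of the vacuolar proton pump fell in 14 of 29 cases with 0 rising (median -0.29, matched lists -0.04, percentile 0, camera adjusted p = 8.9e-07, adjusted p = 0.0184 with an estimated correlation). Genes of ESCRT and Vps proteins, which sort membrane cargo to the lysosome, rose in 19 of 31 cases with 2 falling (median 0.31, matched lists 0.01, percentile 99.98, camera adjusted p = 4.02e-06, adjusted p = 0.0786 with an estimated correlation). Of 8 CCT chaperonin genes 7 rose and 1 fell (median 0.51, camera adjusted p = 0.00183, adjusted p = 0.169 with an estimated correlation), a median within the range of matched lists (median 0.26, 95% of lists -0.23 to 0.67, percentile 90.1). Glutathione S-transferase genes fell in 12 of 34 cases with 2 rising (median -0.14, matched lists -0.04, percentile 0.04, camera adjusted p = 0.000693, adjusted p = 0.0786 with an estimated correlation), and cytochrome P450 genes in 12 of 83 with 4 rising (median -0.10, matched lists -0.02, percentile 0, camera adjusted p = 0.0136, adjusted p = 0.359 with an estimated correlation).

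At 5 h against 0 h, Sm and Lsm genes of the splicing machinery rose in 7 of 9 cases with 0 falling (median 0.53, matched lists 0.24, percentile 98.5, camera adjusted p = 1.66e-12, adjusted p = 0.00034 with an estimated correlation), after 5 of 9 had fallen and 1 risen at 0 h (median -0.44, camera adjusted p = 0.0118, adjusted p = 0.0979 with an estimated correlation, matched lists -0.36, percentile 36.0). Mitochondrial ribosomal protein genes rose in 8 of 64 cases with 0 falling (median 0.14, camera adjusted p = 8e-09, adjusted p = 0.0748 with an estimated correlation), within the range of matched lists (median 0.06, 95% of lists 0.01 to 0.14, percentile 96.5). The Rab, tricarboxylic acid cycle, initiation factor, tRNA synthetase, coat protein and circadian groups did not pass at 0 h against -18 h, with camera adjusted p of 0.106, 0.153, 0.507, 0.156, 0.399 and 0.443.

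The changes of the successive steps correlated at -0.219 across probe sets, which are not independent replicates and share the 0 h arrays. Simulated data without change gave a median of -0.421 from that sharing alone, so the sign of this value carries no information. The covariance of -0.0227 lay below the lowest of 100 simulations (-0.0213), and splitting the 0 h arrays gave a median of -0.0170.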
